A study of Sus scrofa with 40 samples.

How the data were processed

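The series measured gene expression in liver and in the middle layer of backfat over the tenth rib of 20 prepubertal Yorkshire gilts, 6 months old. The pigs came from lines with low (10 pigs) or high (10 pigs) residual feed intake (RFI), the feed eaten beyond what growth and maintenance predict, so that low RFI pigs are the efficient ones. Within each line 5 pigs ate ad libitum and 5 were held at 80% of maintenance for 8 days, which gives 4 groups of 5 in each tissue and 40 arrays in all. Each array was a 1-colour biotin-labelled Affymetrix porcine array, and per the labels the pigs were heterozygous for a variant of MC4R.

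The deposited values are linear intensity per probe set, background-corrected, summarised over probes and scaled per array by the authors. The authors name affy and MAS5 without a version or a role for either. The mean of each array after trimming 2% of the probe sets at each end lay between 500.09 and 500.15, so no further scaling was applied. Of 24123 probe sets, 124 controls were left out, leaving 23999. The platform annotation gave exactly 1 gene symbol to 10069 of them (6765 symbols) and several symbols to 198, while 13732 carried none and are called unnamed. Presence calls and probe-level data were not used here. The arrays give no counts, so their number limits the precision of every value.

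Intensities were log2-transformed without an offset. Within a tissue, a probe set was tested when it exceeded the 40th percentile of its own array on at least 5 of the 20 arrays. A group-means model was fitted to the 20 arrays of each tissue with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. The diet effect is restricted minus ad libitum averaged over both lines, the line effect is low minus high RFI averaged over both diets, and the interaction is the diet effect in low minus that in high RFI pigs. Effects within 1 line or under 1 diet came from the same fit. Whether effects differed between fat and liver was tested on all 40 arrays over the 14001 probe sets tested in both tissues. Overlap between tissues was tested with Fisher's exact test, two-sided.

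Gene lists (41 pathways, complexes and cell type markers) were tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, adjusted over the lists with at least 5 measured genes (40 in liver, 39 in fat). Each gene was represented by its probe set with the highest mean signal in the tissue. Members past the threshold were counted after adjustment over all probe sets and after adjustment over the list alone. Differences in control ratios and marker means were tested by exact permutation of the labels within line, diet or group, two-sided, with every arrangement counted.

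The genes to name were fixed by a rule. It takes the 8 genes with the largest increase and the 8 with the largest decrease among those past the threshold, the 2 members with the smallest p of each list that has a member past it, and, where fewer than 5 probe sets pass, those that pass and the 5 named ones with the smallest p. It adds a fixed set of 24 metabolic genes for diet, given for line as a count. In the account of diet in fat, list members with an adjusted p above 0.00012 were left out unless they belong to the fixed set or the largest changes, and some of them are named where single arrays or the tissues are compared. The groups, comparisons, tests, lists, naming rule and the first group of alternatives below were chosen before the data were examined.

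The alternatives chosen in advance were quantile normalization, no filter, a stricter filter (60th percentile), an offset (20th percentile of all values of the arrays fitted together) before the log, no intensity trend, the replicate number as a block (for the comparison of tissues, arrays of the same group and number as a correlated block, although the labels do not identify the pigs), each array left out in turn and, for lists, an estimated inter-gene correlation and the mean over a gene's probe sets. Chosen after seeing the data were the mean of the skeletal muscle markers as a covariate in fat, only the fat arrays with little muscle or liver signal, only the arrays numbered 1 and 2, only those numbered 3 to 5, and the block together with an estimated correlation. On simulated data with 200 changed probe sets, 77% were recovered in liver (8 false among 162 calls) and 84% in fat (7 false among 175). At a log2 change of 0.5 recovery was 40% in liver and 46% in fat, and at a change of 1 it was 80% and 92%. The simulated noise was drawn independently for each probe set, without resemblance between arrays of the same replicate number. These shares of recovered and false calls need not hold on the real arrays. Tables and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.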

Results

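Expression was measured in liver and backfat of 20 gilts, with 5 pigs in each combination of line (low or high RFI) and diet (ad libitum or restricted), on 40 arrays. Trimmed mean intensity was 500.09 to 500.15 on every array, and the array median ranged from 127 to 191. Arrays numbered 1 and 2 stood apart from those numbered 3 to 5 in both tissues. With group means removed, the first principal component separated these sets and held 21.3% of the variance in liver and 19.1% in fat. The log2 ratio of 3' to 5' actin control probe sets was 2.25 ± 0.28 (SD, n = 8) for numbers 1 and 2 and 1.32 ± 0.194 (n = 12) for numbers 3 to 5 in liver, and 2.27 ± 0.553 and 1.57 ± 0.163 in fat. Both differences had an exact permutation p = 1e-04, the smallest the arrangements can give (adjusted p = 9e-04 over 18 tests). Each set holds pigs of all 4 groups, so counts and list medians for diet and line within each set are given beside the pooled ones. The corresponding GAPDH ratio moved with diet in fat, at 1.88 ± 0.521 (SD, n = 10) in restricted and 1.19 ± 0.365 (n = 10) in ad libitum pigs (exact permutation p = 0.00441, adjusted p = 0.0198), and not detectably in liver (difference 0.15, p = 0.213, adjusted p = 0.548). The log2 array median was also higher in restricted than in ad libitum fat, by 0.107 (exact permutation p = 0.00224, adjusted p = 0.0134).

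The diet comparison asks how the tissues respond to acute caloric restriction. In backfat the fatty acid synthesis list had the lowest median of the lists tested. FASN, the fatty acid synthase, was 6.78-fold lower in restricted pigs (log2 -2.76, SE 0.267, n = 10 per diet, limma adjusted p = 9.13e-07). ME1, a malic enzyme that supplies NADPH, was 6.27-fold lower (log2 -2.65, SE 0.215, adjusted p = 1.94e-07), and SLC25A1, which carries citrate out of mitochondria, was 4.82-fold lower (log2 -2.27, SE 0.202). For these genes every restricted pig lay below every ad libitum pig. ACACA, the acetyl-CoA carboxylase (log2 -1.92, SE 0.292), and SCD, the stearoyl-CoA desaturase (log2 -1.64, SE 0.358), fell too. Of 13 measured fatty acid synthesis genes, 11 fell (11 adjusted over the list alone) and none rose, with a median log2 change of -1.39. The camera adjusted p was 8.95e-11, with adjusted p = 0.299 with an estimated correlation. The list's median was -1.10 within numbers 1 and 2 and -1.38 within numbers 3 to 5.

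In the lists of mitochondrial function more genes of backfat fell than rose, in the same arrays whose GAPDH ratio was higher by 0.69. Of 59 genes of oxidative phosphorylation 46 fell (50 adjusted over the list alone) and none rose, with a median of -0.65 (camera adjusted p = 1.58e-23, adjusted p = 0.299 with an estimated correlation). NDUFA10, of respiratory complex I, changed by -1.06 (SE 0.101) and SDHC, of complex II, by -1.09 (SE 0.11), and for both no restricted pig overlapped an ad libitum pig. The median was -0.55 within numbers 1 and 2 and -0.73 within numbers 3 to 5. Of 22 TCA cycle genes 15 fell and 1 rose (16 and 1 adjusted over the list alone), among them PDHB of pyruvate dehydrogenase at -1.63 (SE 0.154) and malate dehydrogenase MDH2 at -1.12 (SE 0.137). This list's median was -0.51 (camera adjusted p = 3.6e-07, adjusted p = 0.299 with an estimated correlation), and -0.40 and -0.53 within the sets of numbers. In fatty acid oxidation 12 of 27 genes fell and 3 rose (13 and 3 adjusted over the list alone, median -0.30, within the sets of numbers -0.28 and -0.26, camera adjusted p = 0.00122, adjusted p = 0.299 with an estimated correlation). ECI1, an enoyl-CoA isomerase, changed by -1.38 (SE 0.109) and ACADL, an acyl-CoA dehydrogenase, by -0.88 (SE 0.0982), while CPT1A, which admits fatty acids to mitochondria, rose by 0.43 (SE 0.149, adjusted p = 0.0378), a call lost under 12 of 26 alternatives.

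Other biosynthetic and housekeeping lists of backfat had more members lower than higher. In cholesterol synthesis 9 of 14 genes fell and none rose (11 fell adjusted over the list alone, median -0.60, camera adjusted p = 2.06e-05, adjusted p = 0.299 with an estimated correlation), with FDPS at -1.31 (SE 0.172) and the sterol demethylase CYP51 at -1.25 (SE 0.161). Amino acid catabolism had 11 of 19 genes lower and none higher (11 adjusted over the list alone, median -0.55, camera adjusted p = 0.000116, adjusted p = 0.299 with an estimated correlation). Both named members act on branched-chain amino acids, BCKDHB at -1.23 (SE 0.158) and BCAT2 at -0.99 (SE 0.13). The proteasome had 20 of 40 genes lower and none higher (22 lower and 2 higher adjusted over the list alone, median -0.26, camera adjusted p = 1.38e-05, adjusted p = 0.388 with an estimated correlation), for example PSMB5 at -0.74 (SE 0.0912). Antioxidant genes had 11 of 27 lower and 1 higher (12 and 2 adjusted over the list alone, median -0.41, camera adjusted p = 0.00105, adjusted p = 0.299 with an estimated correlation), with the quinone reductase NQO1 at -1.28 (SE 0.168) and the peroxiredoxin PRDX2 at -0.55 (SE 0.0731). Triglyceride synthesis had 6 of 15 lower and none higher (6 adjusted over the list alone, median -0.15, camera adjusted p = 0.0103, adjusted p = 0.299 with an estimated correlation), among them the acyltransferase DGAT2 at -0.97 (SE 0.144). Cell cycle genes had 10 of 19 lower and none higher (10 lower and 3 higher adjusted over the list alone, median -0.47, camera adjusted p = 0.0108, adjusted p = 0.387 with an estimated correlation, 0.444 with the stricter filter). Medians within numbers 1 and 2 and within numbers 3 to 5 were -0.62 and -0.61 for cholesterol synthesis, -0.70 and -0.44 for amino acid catabolism, and -0.27 and -0.28 for the proteasome. They were -0.43 and -0.29 for antioxidant genes, -0.28 and -0.14 for triglyceride synthesis, and -0.63 and -0.37 for the cell cycle.

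The largest decreases outside these groups were PGLYRP2 (log2 -2.70, SE 0.255), the fructose transporter SLC2A5 (-2.58, SE 0.308), STAR, which moves cholesterol into mitochondria (-2.55, SE 0.297), ECHDC1 (-2.45, SE 0.184) and AKR1CL1 (-2.30, SE 0.191). Creatine kinase CKB (3.99-fold lower, SE 0.297 on the log2 scale), the hexokinase HK1 (-1.13, SE 0.164), LUM (-1.13, SE 0.157), AMACR (-1.02, SE 0.107), the enolase ENO1 (-0.82, SE 0.124) and COL15A1 (-0.75, SE 0.0953) also fell. Glycolysis had 5 of 19 genes lower and 1 higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.139). Extracellular matrix genes split, with 7 of 35 higher and 6 lower (7 and 6 adjusted over the list alone, camera adjusted p = 0.897, median 0.03, within the sets of numbers 0.12 and 0.01, mean -0.03).

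Genes that rose in restricted backfat were led by CYP2B22, a cytochrome P450, at 4.17-fold (log2 2.06, SE 0.322, adjusted p = 0.000123). It was followed by APOD, a lipocalin (log2 1.95, SE 0.323), ABCA1, the cholesterol exporter (1.86, SE 0.207), ITIH1 (1.75, SE 0.443), DPP4 (1.57, SE 0.197), PRR15 (1.54, SE 0.325), HSD11B1, which regenerates active glucocorticoid (2.83-fold higher, SE 0.2 on the log2 scale), and LPCAT4 (1.45, SE 0.353). For ABCA1 and HSD11B1 no restricted pig overlapped an ad libitum pig. CTSK, a cysteine protease (0.69, SE 0.0729), CFD, the adipocyte product adipsin (0.62, SE 0.0968), EIF4B (0.57, SE 0.0886) and FKBP5, a glucocorticoid-induced gene (0.65, SE 0.216, call lost under 5 of 26 alternatives), rose as well.

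Of 19 acute phase and complement genes 8 rose in restricted backfat and none fell (11 higher and 1 lower adjusted over the list alone). Their median was 0.74 (camera adjusted p = 0.000442, adjusted p = 0.386 with an estimated correlation), and 0.43 within numbers 1 and 2 and 1.02 within numbers 3 to 5. The complement proteases C1S (0.71, SE 0.08) and C1R (0.84, SE 0.131) were higher in every restricted pig than in any ad libitum pig. Hepatocyte markers had 2 of 9 members higher, including APOA1 at 0.82 (SE 0.123), and none lower (2 adjusted over the list alone, median 0.82, within the sets of numbers 0.57 and 1.07, camera adjusted p = 0.038, adjusted p = 0.701 with an estimated correlation). One array, low RFI restricted replicate 5, had a hepatocyte marker mean of 12.3 on the log2 scale against 7.13 to 9.54 on the other 19 fat arrays. Without it 9 acute phase genes passed, with a median of 0.55, and the hepatocyte list ended at a median of 0.43 and a camera adjusted p of 0.184.

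In total 3999 of 15498 probe sets (25.8%) changed with diet in backfat by limma, 2344 higher and 1655 lower, and changes over 2-fold were more often decreases (206 lower, 104 higher). They covered 1666 named genes, of which 10 had called probe sets in opposite directions. The excess of increases rests on scaling, since quantile normalization gave 1823 higher and 1906 lower, and the median over all probe sets was 0.08 before and 0.02 after it. Within numbers 1 and 2 the count was 469, and within numbers 3 to 5 it was 2908. With the GAPDH and actin ratios as covariates it was 1840. Of 39 lists tested 14 were called at the preset correlation and 0 with an estimated one, and 10 of 100 splits of the fat arrays into other diet groups, the real one included, called as many. Among the fixed genes, LPL, the lipase that releases fatty acids from lipoproteins, fell by 0.40 (SE 0.0895). The hormone genes LEP (-0.24, SE 0.406, adjusted p = 0.716) and ADIPOQ (0.13, SE 0.0947, adjusted p = 0.35), the lipases LIPE (-0.22, SE 0.201) and PNPLA2 (0.07, SE 0.153), PCK1 (0.41, SE 0.48), PDK4 (0.19, SE 0.264), SREBF1 (-0.07, SE 0.266), IGF1 (-0.41, SE 0.171, adjusted p = 0.0874) and IGFBP2 (0.05, SE 0.709) did not pass. None of 9 lipolysis genes passed, over all probe sets or adjusted over the list alone (limma, camera adjusted p = 0.821). The brightest probe set of the phosphatidate phosphatase LPIN1 did not pass (-0.15, adjusted p = 0.412), whereas another of its probe sets did (-0.85, adjusted p = 0.00369).

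**Figure D1:**
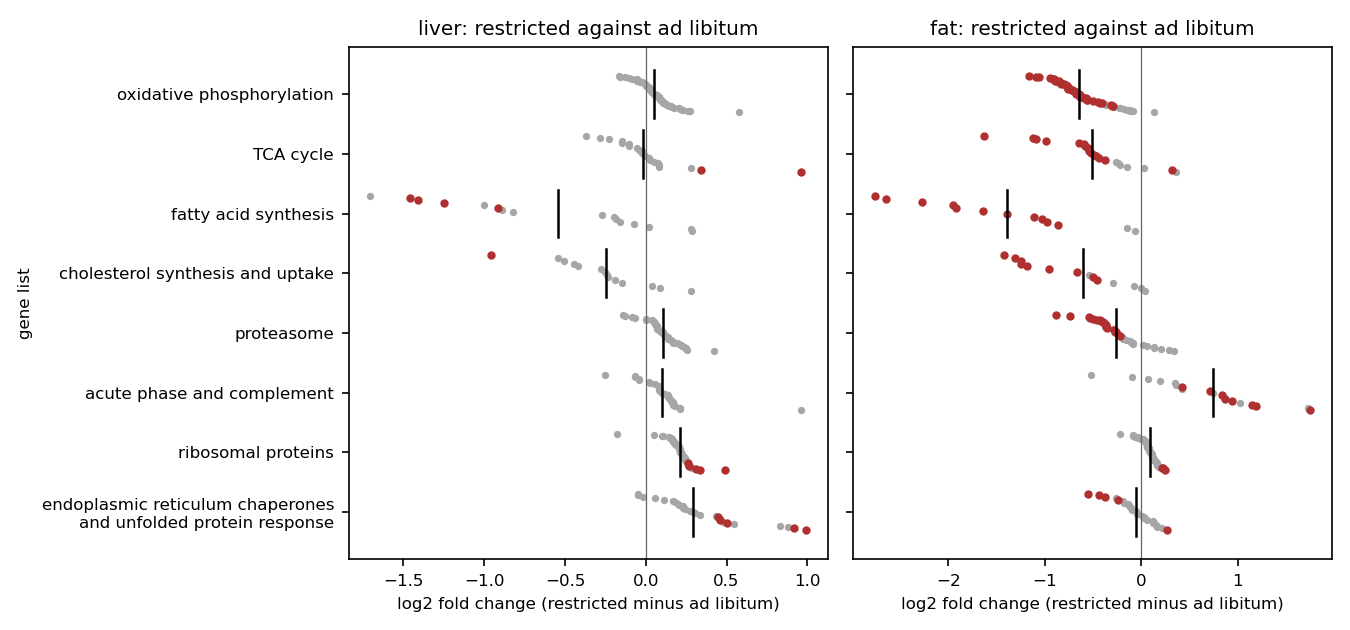
Log2 change with restriction (restricted minus ad libitum) of each measured member of 8 gene lists in liver and in fat, with red dots for genes at a limma adjusted p under 0.05, grey dots for the others and a black bar at each list's median. In fat the oxidative phosphorylation genes centre on -0.65 and the fatty acid synthesis genes on -1.39, while in liver the ribosomal protein genes centre on 0.21.

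In liver, a smaller set of lipid genes fell with restriction, and 5 of 27 endoplasmic reticulum chaperone genes rose. LPIN1 was 2.83-fold lower (log2 -1.50, SE 0.289, n = 10 per diet, limma adjusted p = 0.0171). The fatty acid elongase ELOVL6 (-1.46, SE 0.301), the acetyl-CoA synthetase ACSS2 (-1.41, SE 0.23), FASN (-1.25, SE 0.28, adjusted p = 0.0343) and ME1 (-0.92, SE 0.214, adjusted p = 0.0422) fell with it. Of 16 fatty acid synthesis genes 4 fell (6 adjusted over the list alone) and none rose, with a median of -0.54 (camera adjusted p = 2.63e-06, adjusted p = 0.0783 with an estimated correlation). That median was -0.13 within numbers 1 and 2 and -0.82 within numbers 3 to 5. Cholesterol synthesis had 1 of 14 genes lower, the sterol reductase TM7SF2 (-0.96, SE 0.217), and 3 lower adjusted over the list alone. Its median of -0.25 (camera adjusted p = 0.000396, adjusted p = 0.241 with an estimated correlation) was -0.03 within numbers 1 and 2 and -0.49 within numbers 3 to 5. ACACA (-1.71, SE 0.599, adjusted p = 0.205), SCD (-0.82, SE 0.334), CYP7A1, which starts bile acid synthesis (-0.91, SE 0.452), CPT1A (-0.53, SE 0.206), PPARGC1A (-0.49, SE 0.186), PCK1 (-0.22, SE 0.301), PDK4 (-0.07, SE 0.122), PNPLA2 (-0.17, SE 0.168), SREBF1 (0.29, SE 0.198), FKBP5 (-0.01, SE 0.233), IGF1 (-0.26, SE 0.195), IGFBP1 (-0.15, SE 0.531) and IGFBP2 (0.50, SE 0.276) did not pass.

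The largest increases in liver were GMPPB, which makes GDP-mannose for glycosylation (log2 1.67, SE 0.345), LRRN3 (1.15, SE 0.22), PGM3, which makes precursors of N-glycans (1.04, SE 0.168), the endoplasmic reticulum proteins SDF2L1 (0.99, SE 0.211), MANF (0.91, SE 0.186) and LRRC59 (0.80, SE 0.169), pyruvate carboxylase PC (0.96, SE 0.206) and LOC100154873 (0.81, SE 0.117). Endoplasmic reticulum chaperones had 5 of 27 genes higher and none lower (14 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 4.11e-11, adjusted p = 0.0783 with an estimated correlation). Of 59 ribosomal protein genes 5 rose, among them RPS12 (0.33, SE 0.0642) and RPLP2 (0.49, SE 0.0964), and none fell, with 47 higher adjusted over the list alone and a median of 0.21 (camera adjusted p = 5.19e-27, adjusted p = 0.0783 with an estimated correlation). Translation factors had no member past the threshold in limma and 5 of 30 higher adjusted over the list alone (median 0.15, camera adjusted p = 0.000286, adjusted p = 0.05 with an estimated correlation). Heat shock genes had 1 of 17 higher (4 adjusted over the list alone, median 0.20, camera adjusted p = 0.000225, adjusted p = 0.0783 with an estimated correlation). That gene, the chaperone HSP90AA1, had 1 probe set at 0.36 (adjusted p = 0.0423) and another at -0.47 (adjusted p = 0.0355). Medians within numbers 1 and 2 and within 3 to 5 were 0.27 and 0.30 for the chaperones and 0.19 and 0.23 for ribosomal proteins. They were 0.13 and 0.19 for translation factors and 0.24 and 0.20 for heat shock genes. ACO1, an aconitase, at 0.34 (SE 0.0677) and lactate dehydrogenase LDHB at 0.56 (SE 0.115) also rose.

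Of 32 extracellular matrix genes 2 fell in restricted liver and none rose (7 lower adjusted over the list alone). The median was -0.25 (camera adjusted p = 5.62e-07, adjusted p = 0.0228 with an estimated correlation), and -0.22 and -0.24 within the sets of numbers. COL6A3, a collagen VI chain, changed by -0.86 (SE 0.0987, adjusted p = 0.000166), with every restricted pig below every ad libitum pig, and fibrillin FBN1 by -0.55 (SE 0.13). Cell cycle genes had 2 of 23 lower and none higher (7 lower and 2 higher adjusted over the list alone, median -0.44, camera adjusted p = 7.29e-06, adjusted p = 0.0783 with an estimated correlation, 0.0533 with the stricter filter), namely the topoisomerase TOP2A (-1.05, SE 0.177) and NUSAP1 (-0.76, SE 0.166). Glucocorticoid-responsive genes had 1 of 20 lower and none higher (5 lower and 1 higher adjusted over the list alone, median -0.24, camera adjusted p = 0.000225, adjusted p = 0.05 with an estimated correlation), the glucocorticoid-induced TSC22D3 (-0.81, SE 0.128). Clock genes had 1 of 8 lower, the deubiquitinase USP2 (-1.51, SE 0.271), and 3 lower and 1 higher adjusted over the list alone (median -0.38, camera adjusted p = 0.00442, adjusted p = 0.05 with an estimated correlation). TP53INP2 (-1.29, SE 0.287), ECHDC1 (-1.08, SE 0.136), the adiponectin receptor ADIPOR2 (-0.80, SE 0.13) and the peroxiredoxin PRDX6 (-0.45, SE 0.103) also fell. Hepatocyte markers had no member past the threshold in limma among 24, over all probe sets or adjusted over the list alone (camera adjusted p = 0.00475, adjusted p = 0.63 with an estimated correlation). Their median of 0.11, and 0.02 and 0.16 within the sets of numbers, turned to 0.01 with a lower direction after quantile normalization. Medians within numbers 1 and 2 and within 3 to 5 were -0.31 and -0.40 for the cell cycle. They were -0.16 and -0.28 for glucocorticoid-responsive genes and -0.12 and -0.48 for clock genes.

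By limma 144 of 15677 probe sets changed with diet in liver, 59 higher and 85 lower, in 79 named genes. Within numbers 1 and 2 no probe set passed in limma, and within numbers 3 to 5 the count was 44. The replicate block gave 328 and a fit without the intensity trend gave 74. Leaving out high RFI ad libitum replicate 1, 4 or 5 gave 73, 68 or 83. Leaving out high RFI restricted replicate 2, 4 or 5 gave 95, 76 or 56, and leaving out low RFI ad libitum replicate 3, 4 or 5 gave 89, 89 or 78. Of 26 alternatives (25 for TP53INP2 and GMPPB), the call was lost under 19 for HSP90AA1, 18 for FBN1, 17 for PRDX6, 16 for ME1, 13 for TM7SF2, 12 for FASN, 10 for TP53INP2, and 6 for SDF2L1. It was lost under 5 each for PC, LRRC59 and NUSAP1, 2 for LDHB, and 1 each for ELOVL6, GMPPB, MANF and RPS12. The adjusted p-values reached 0.0944. Of 40 lists tested 17 were called at the preset correlation and 1, extracellular matrix, with an estimated one, and 5 of 100 splits of the liver arrays, the real one included, called as many.

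**Figure D2:**
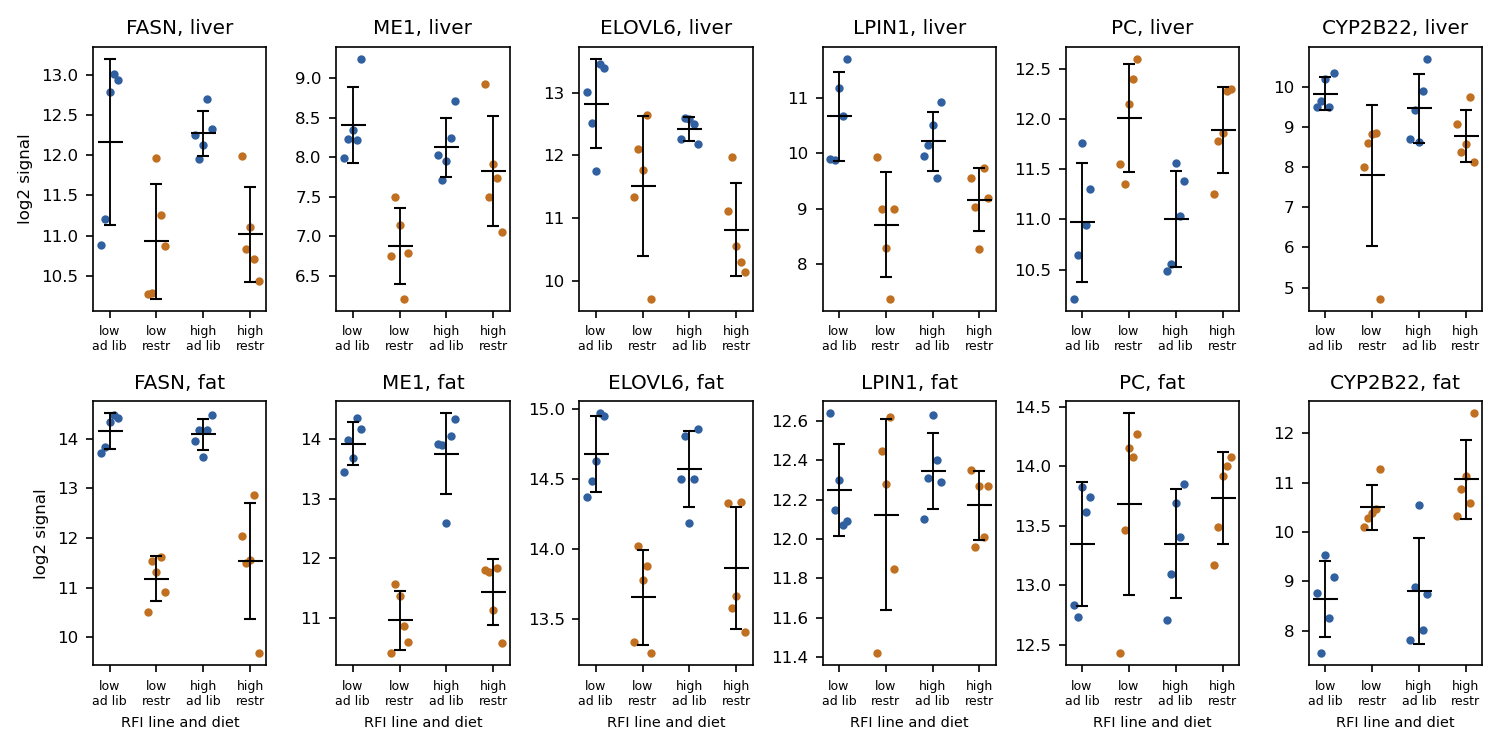
Log2 signal on each array of FASN, ME1, ELOVL6, LPIN1, PC and CYP2B22 in liver and fat by line and diet, with blue points for ad libitum, orange points for restricted pigs and black marks for the mean ± SD of the 5 arrays. FASN in fat separates the diets in both lines (log2 -2.76 overall), while the liver groups overlap.

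Restriction was also examined within each line, and the interaction asks whether lines that differ in feed efficiency respond differently. In backfat 1426 probe sets changed in low RFI pigs (678 higher, 748 lower) and 1398 in high RFI pigs (693 higher, 705 lower). No probe set passed the interaction test in limma, where 244 had an unadjusted p under 0.05 and 775 would by chance. The smallest interaction p-values in fat belonged to PTP4A2 (-0.95, SE 0.18, adjusted p = 0.514), SLA-DOA (-1.51, SE 0.367), SLC9A5 (2.53, SE 0.636), TK2 (0.82, SE 0.207) and TRMT61A (-1.93, SE 0.524). In low RFI fat, leaving out low RFI ad libitum replicate 4 gave 839. For high RFI fat, leaving out ad libitum replicate 1, 3, 4 or 5 gave 892, 2239, 834 or 757, leaving out restricted replicate 5 gave 832, and the arrays with little muscle or liver signal (5 ad libitum, 3 restricted) gave 391. The replicate block gave 2207 and 2184.

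In liver 21 probe sets changed in low RFI pigs (5 higher, 16 lower) and 4 in high RFI pigs (all lower, COL6A3 at -0.81 with adjusted p = 0.0404 and 3 unnamed). No probe set passed the liver interaction in limma (525 at an unadjusted p under 0.05 against 784 by chance), and 1 passed without low RFI ad libitum replicate 3, so these counts do not show that the lines differ. The 5 named genes with the smallest interaction p were DFFA (0.95, SE 0.226), ENTPD4 (1.15, SE 0.289), KIAA0586 (-1.64, SE 0.426), TMCO3 (-1.02, SE 0.263) and PCMTD1 (-0.70, SE 0.198), none past the threshold (adjusted p = 0.999). The low RFI count was 7 without low RFI ad libitum replicate 3, 9 without replicate 5 of that group and 12 without low RFI restricted replicate 3. For high RFI the count was 7 without low RFI restricted replicate 5, and 0, 1 or 2 without any of the other arrays except low RFI restricted replicates 1 and 3 and low RFI ad libitum replicate 5. It was also 0 with the block and 0 without the trend. Camera called 6 lists for the interaction in liver and 4 in fat, with adjusted p-values no lower than 0.245 and 0.972 with an estimated correlation. The liver count was 3 without low RFI ad libitum replicate 5 and 3 after quantile normalization, and the fat count 7 without low RFI ad libitum replicate 1 or low RFI restricted replicate 2, and 2 without high RFI restricted replicate 4 or low RFI ad libitum replicate 4 or 5. Of these the fatty acid synthesis list in fat had a median of -0.26 (camera adjusted p = 0.00305, adjusted p = 0.972 with an estimated correlation, lost under 6 further alternatives with values up to 0.325). Immediate early genes in fat had one of -0.51 (3.06e-05, adjusted p = 0.972 with an estimated correlation), and the chaperones in liver one of 0.25 (0.00272, adjusted p = 0.773 with an estimated correlation, lost under 1 further alternative at 0.0508). No member of these 3 lists passed the interaction in limma, over all probe sets or adjusted over the list alone.

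The tissues shared part of the decrease. Among 14001 probe sets tested in both, 30 were lower in both against 8.48 expected if calls were independent (Fisher's exact p = 1.58e-10). The Fisher p-values here are descriptive, since probe sets are not independent and both tissues come from the same 20 gilts. The 30 include the lipid genes FASN, ME1, ELOVL6, ACSS2, LPIN1 and TM7SF2, as well as ADIPOR2, ECHDC1, PRDX6, TP53INP2, TOP2A and NUSAP1. For LPIN1 the shared call belongs to a probe set other than its brightest one in fat, which did not pass (-0.15, limma adjusted p = 0.412). Higher in both were 12, against 7.70 expected (Fisher's exact p = 0.114), and 15 were called in opposite directions. Across these probe sets, which are not independent replicates, the diet effects in the tissues correlated at Pearson r = 0.224 and Spearman rho = 0.164. The diet effect differed between tissues for 1524 probe sets, 634 with the fat effect above the liver effect and 890 below, and for 2296 with arrays of the same group and number as a block. The labels do not identify the pigs, and for numbers 1 and 2 the best matched liver and fat arrays had the other number in 7 of 8 cases. FASN fell further in fat by 1.51 (log2 difference -1.51), and 44 of 59 oxidative phosphorylation genes and 18 of 40 proteasome genes had a lower effect in fat with none having a higher one. CYP2B22 differed by 3.42, with a liver change of -1.36 (SE 0.412, adjusted p = 0.128) that did not pass.

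The line comparison asks what differs between the low RFI and the high RFI line. The design does not separate feed efficiency from other differences between the lines. In liver PON3, a paraoxonase carried on high-density lipoprotein, was 7.61-fold lower in low RFI pigs (log2 -2.93, SE 0.355, n = 10 per line, limma adjusted p = 0.000704). ACP5, an acid phosphatase of macrophages and osteoclasts, was 2.13-fold lower (-1.09, SE 0.176, adjusted p = 0.0116), and the macrophage glycoprotein GPNMB was 1.67-fold lower (-0.74, SE 0.104, adjusted p = 0.00236). These calls held under each of 26 alternatives. A less bright probe set of the lysosomal enzyme HGSNAT was lower (-1.80, SE 0.328, adjusted p = 0.042), and its brightest one did not pass (-0.67, adjusted p = 0.572). With 3 unnamed probe sets the limma count was 7 (2 higher, 5 lower), 4 within numbers 1 and 2 and 2 within numbers 3 to 5. None of the 16 fixed metabolic genes measured in liver passed for line (limma, 1024 probe sets at an unadjusted p under 0.05).

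Under restriction alone, 3 liver probe sets differed between lines, PON3 (-3.45, adjusted p = 0.0126), HGSNAT (-2.70, adjusted p = 0.0443) and 1 unnamed. The count was 6 with the block, 5 without low RFI ad libitum replicate 4, 1 without low RFI restricted replicate 1 or 2 or high RFI restricted replicate 3, and 0 without high RFI restricted replicate 1 or low RFI restricted replicate 5. Under ad libitum feeding no liver probe set passed in limma (786 at an unadjusted p under 0.05), and 1 passed without low RFI ad libitum replicate 1, 2, 4 or 5. Camera called antigen presentation genes lower in low RFI liver (median -0.24, adjusted p = 0.00421, adjusted p = 0.87 with an estimated correlation), with none of 19 members past the threshold in limma, over all probe sets or adjusted over the list alone. Lymphocyte markers (median -0.14, camera adjusted p = 0.062) and macrophage markers (-0.17, adjusted p = 0.109) were not called, with no member past the limma threshold (0 and 0 adjusted over the list alone). Amino acid catabolism was called lower (median -0.11, adjusted p = 0.00548, adjusted p = 0.87 with an estimated correlation, lost under 1 further alternative at 0.0797), with none of 31 members past the limma threshold and 3 lower adjusted over the list alone. The cell cycle list was called higher (median 0.15, adjusted p = 0.0196, adjusted p = 0.87 with an estimated correlation), with none of 23 members passing in either count, and this call was lost under 7 further alternatives (adjusted p up to 0.331). As many lists were called by 75 of 100 splits of the liver arrays, the real one included. This count of 3 lists was 5 without high RFI restricted replicate 1 or high RFI ad libitum replicate 2, 9 without low RFI restricted replicate 4, 1 without high RFI ad libitum replicate 4, 6 without low RFI ad libitum replicate 5 and 5 with the block. Medians within numbers 1 and 2 and within 3 to 5 were -0.17 and -0.21, -0.23 and -0.06, and 0.21 and 0.07 for these 3 lists.

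In backfat, TMEM254, a membrane protein, was 1.67-fold lower in low RFI pigs (log2 -0.74, SE 0.0914, n = 10 per line, limma adjusted p = 0.00114) and was the only named gene of 3 probe sets that passed. It differed between tissues as well (fat minus liver -0.84, adjusted p = 0.0173), with 4 unnamed probe sets. GPD2, the mitochondrial glycerol phosphate dehydrogenase (-0.63, SE 0.121, adjusted p = 0.0914), GPM6B (-0.61, SE 0.115), the sodium pump subunit ATP1B1 (0.59, SE 0.12, adjusted p = 0.119) and CD47 (0.38, SE 0.077) did not pass. None of the 17 fixed metabolic genes measured in fat passed for line (limma, 1205 probe sets at an unadjusted p under 0.05). The count of 3 was 20 with the replicate block, 1 without the filter, 1 with the muscle marker mean as a covariate, 1 within numbers 1 and 2 and 2 within numbers 3 to 5. It was 1 without high RFI ad libitum replicate 1, 2 or 5, high RFI restricted replicate 1, low RFI ad libitum replicate 1 or 3, or low RFI restricted replicate 3 or 4, and 7 without high RFI restricted replicate 5. The count for both tissues compared, 5, was 3 without fat high RFI restricted replicate 1, 2 without fat low RFI restricted replicate 1, fat high RFI ad libitum replicate 2, fat low RFI ad libitum replicate 4 or liver high RFI ad libitum replicate 4, and 8 without fat low RFI restricted replicate 5.

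Skeletal muscle markers had the largest list difference between lines in backfat, with a median of 2.18 (camera adjusted p = 1.86e-13, adjusted p = 0.644 with an estimated correlation), 3.46 within numbers 1 and 2 and 1.25 within numbers 3 to 5. None of the 24 markers passed in limma, over all probe sets or adjusted over the list alone. The signal varied widely between arrays, and the creatine kinase CKM ran from 6.89 to 14.2 on the log2 scale. The marker mean was 9.36 ± 2.68 (SD, n = 10) in low and 7.33 ± 1.77 (n = 10) in high RFI pigs (exact permutation p = 0.0668, adjusted p = 0.454 over 34 tests). Camera called 11 of 39 lists for line in fat, among them ribosomal proteins (median 0.11, adjusted p = 3.89e-13, adjusted p = 0.644 with an estimated correlation), acute phase genes (0.22, adjusted p = 0.000459, adjusted p = 0.644 with an estimated correlation) and fatty acid synthesis (-0.19, adjusted p = 0.0201, adjusted p = 0.696 with an estimated correlation, lost under 6 further alternatives). The fat array with the high hepatocyte marker mean belongs to the low RFI line. Without it the acute phase adjusted p was 0.0427. No member of these 3 lists passed for line in limma, over all probe sets or adjusted over the list alone. The count of 11 was 7 after quantile normalization or with the stricter filter, 6 without low RFI restricted replicate 1, 7 without high RFI restricted replicate 2 or low RFI restricted replicate 3, and 5 without high RFI ad libitum replicate 4. The medians of these 3 lists within numbers 1 and 2 and within 3 to 5 were -0.02 and 0.21, 0.06 and 0.46, and -0.50 and 0.02, so the first and the last turn sign between the sets.

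**Figure D3:**
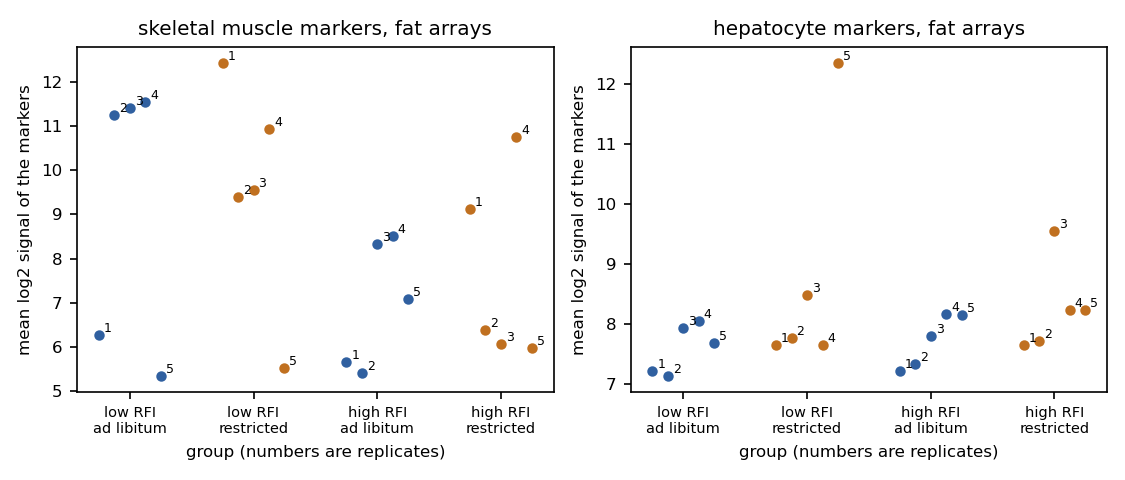
Mean log2 signal of the skeletal muscle markers and of the hepatocyte markers on each fat array by line and diet, with the replicate number beside each point. The muscle mean runs from 5.35 to 12.4, and low RFI restricted replicate 5 has a hepatocyte mean of 12.3.

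Within diets, 2 fat probe sets differed between lines under ad libitum feeding, TMEM254 (-0.86, adjusted p = 0.0222) and 1 unnamed, and none did under restriction in limma (747 at an unadjusted p under 0.05). The ad libitum count was 0 with the muscle covariate, 0 on the arrays with little muscle or liver signal, 1 with the block, 0 without low RFI ad libitum replicate 1 or 5 or high RFI ad libitum replicate 2, 4 or 5, and 1 without low RFI ad libitum replicate 2. Under restriction 1 passed without low RFI restricted replicate 3.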

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

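The tests of explanations in this part, and the predictions for the other splits of the arrays, were written after the results were seen.

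Camera called skeletal muscle markers higher in the fat of low RFI pigs (median 2.18, adjusted p = 0.644 with an estimated correlation), with none of 24 past the limma threshold. Within groups, 23 of the 24 markers correlated above 0.5 with the mean of the others across the fat arrays (median r 0.945), and 8 of the 24 were also measurable in liver. CKM reached 14.2 and MYH2 14 on the log2 scale, so skeletal muscle in some of the sampled backfat is a candidate source. Against a line difference present in every low RFI pig, only 5 of 10 low RFI arrays had a marker mean above that of every high RFI array, and the difference of 2.03 had an exact permutation p of 0.0668. With the marker mean as a covariate 1 probe set passed (TMEM254, line in fat, adjusted p 0.00884), and a line difference in how much muscle lies in or near the sampled layer stays open and untested.

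In restricted fat 8 of 19 acute phase genes and 2 of 9 hepatocyte markers were higher (camera adjusted p = 0.000442, adjusted p = 0.386 with an estimated correlation, and 0.038, adjusted p = 0.701 with an estimated correlation), and 1 array, low RFI restricted replicate 5, stood apart with ALB at 14.6 (highest other fat array 11.3) and TF at 13.1 (highest other 10.4). Liver RNA in that array could raise these lists. As the whole cause of the acute phase change it is excluded, since without the array 9 of 19 members passed (8 with it, all 8 in both) and the median went from 0.74 to 0.55. For the hepatocyte markers, 2 of which are also acute phase genes, the same 2 of 9 members still passed, but the list's call ended (camera adjusted p 0.038 with and 0.184 without the array, adjusted p = 0.701 with an estimated correlation) as its median went from 0.82 to 0.43. A response of fat to restriction stays open for the members that passed without the array, and liver RNA in that array stays open for the rest.

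In restricted fat 46 of 59 oxidative phosphorylation and 11 of 13 fatty acid synthesis genes were lower (adjusted p = 0.299 with an estimated correlation for both lists), where the log2 GAPDH ratio of 3' to 5' signal, a measure outside the comparisons, was higher by 0.691. RNA quality is argued against as the whole cause: with both control ratios as covariates 50 of the 57 called members still passed, and their median went from -0.77 to -0.60, although over all probe sets 1840 passed against 3999, so that part of the wider count may move with the ratios. The oxidative phosphorylation mean relative to the adipocyte marker mean still differed by -0.445 (exact permutation p = 0.0051). The fatty acid synthesis mean relative to the same marker mean differed by -1.28 (exact permutation p = 3.15e-05). Both argue against a smaller share of adipocytes only if the adipocyte markers do not themselves respond to restriction, which was not tested. Each diet group holds the same replicate numbers, so a shift between numbers 1 and 2 and numbers 3 to 5 cannot by itself give the fall of these genes. The smallest median of either list within either set was 79.1% of its median over all arrays. Skeletal muscle markers differed by diet in opposite directions within the sets (median 2.45 within numbers 1 and 2, -0.52 within numbers 3 to 5). Both lists fell in both sets (oxidative phosphorylation -0.55 and -0.73, fatty acid synthesis -1.10 and -1.38). With the muscle marker mean as a covariate, 3956 probe sets passed for diet in fat. These values argue against muscle as the whole cause of the fall of these genes. A response of these genes to restriction is therefore a hypothesis consistent with the tests run here, found and tested on the same arrays.

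Single arrays far from the other 4 of their group were found in 57 of 644 groups of values examined, where chance gives about 5%, and each value below is the gap to the nearest array over the range of the group. Fat high RFI ad libitum replicate 3 carried 11 of them, the lowest for AKR1CL1 (0.736), BECN1 (0.768), ECHDC1 (0.761), GOT1 (0.809), HSPE1 (0.713), ME1 (0.751), PDHB (0.808), SDHC (0.743) and SLA-DMA (0.774) and the highest for APOD (0.834) and DNAJB9 (0.746). All of these but DNAJB9 lay in the direction of the restriction effect. The log2 GAPDH ratio of this array was 1.81, the highest among the ad libitum fat arrays. Mean ratios were 1.88 in restricted and 1.19 in ad libitum fat. Whether RNA quality sets this array apart was not tested. In other high RFI ad libitum fat arrays such values were APOA1 (0.727) and PDK4 (0.853) lowest in replicate 2, RGS5 (0.828) lowest in replicate 4 and ITIH1 (0.787) lowest in replicate 5. In high RFI restricted fat they were LEP (0.773) highest and PDK4 (0.791) lowest in replicate 3, and, in replicate 5, KLRK1 (0.737), PGLYRP2 (0.764) and SCD (0.808) lowest and RGS5 (0.773) highest. In low RFI ad libitum fat they were BTG1 (0.717), CD47 (0.737) and PCK1 (0.773) highest in replicate 1, AMACR (0.807) highest and RBP4 (0.716) lowest in replicate 2, C1R (0.765) highest in replicate 3, and ADIPOQ (0.755) and GBP1 (0.778) highest and the macrophage marker mean (0.737) lowest in replicate 5. In low RFI restricted fat they were CKB (0.778), EIF4B (0.715), SLC25A1 (0.765) and SREBF1 (0.761) lowest in replicate 1, ADIPOQ (0.719) lowest and CYP51 (0.812), HBB (0.766) and the actin ratio (0.863) highest in replicate 2, NQO1 (0.833) highest in replicate 3, and SLC2A5 (0.829) lowest and the hepatocyte marker mean (0.821) highest in replicate 5.

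In liver such values were FKBP5 (0.714) highest and GMPPB (0.838) and IGFBP1 (0.874) lowest in high RFI ad libitum replicate 1, and LRRC59 (0.713) and RPLP2 (0.712) highest in replicate 2 of that group. In high RFI restricted liver they were IGFBP1 (0.831) and PCK1 (0.806) lowest in replicate 3, the lymphocyte marker mean (0.925) highest in replicate 4 and MANF (0.718) highest in replicate 5. In low RFI liver they were PON3 (0.879) highest in ad libitum replicate 4, ME1 (0.712) highest in ad libitum replicate 5, TP53INP2 (0.851) lowest in restricted replicate 2, SREBF1 (0.726) highest in restricted replicate 3, ACACA (0.842) highest in restricted replicate 4, and PON3 (0.741) and TSC22D3 (0.799) lowest in restricted replicate 5.

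The diet effect differed between fat and liver, by a test of the difference itself, for 1524 probe sets, and the line effect for 5. Among the named genes the diet effect in fat exceeded that in liver by a log2 difference of 3.42 for CYP2B22, 1.89 for ABCA1, 1.67 for ITIH1, 1.30 for DPP4 and HSD11B1, 1.10 for LPIN1, 1.05 for TSC22D3, 1.04 for COL6A3, 0.96 for CPT1A, 0.927 for FBN1, 0.829 for EIF4B, 0.705 for RBP4, 0.699 for CTSK, 0.675 for C1R, 0.665 for APOA1, 0.558 for C1S and 0.456 for CFD. The LPIN1 value compares the tissues on a single probe set, whereas its brightest probe sets in liver and in fat are not the same. The difference was -3.09 for PGLYRP2, -2.43 for CKB, -2.11 for SLC25A1, -2.10 for AKR1CL1, -1.73 for ME1, -1.69 for CDKN1A, -1.57 for PDHB, -1.51 for FASN, -1.41 for BCAT2 and LRRN3, -1.37 for ECHDC1, -1.27 for BCKDHB, -1.16 for AMACR and PGM3, -1.12 for SDHC, -1.11 for MDH2, -1.10 for LRRC59, -1.07 for FDPS and HK1, -1.06 for NDUFA10, and -1.01 for ECI1, MANF and NQO1. It was -0.895 for ACADL, -0.878 for LOC100154873, -0.803 for ENO1, -0.802 for CYP51, -0.791 for PSMB5, -0.781 for DNAJB9, -0.769 for HSPE1, -0.607 for PSMB7, -0.596 for GOT1, -0.573 for PRDX2, -0.507 for HSP90AA1, -0.497 for ASNS, -0.468 for MDH1 and -0.462 for HSPD1.

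Each count was compared with 100 splits of the same arrays into groups of the same sizes, the real one included, drawn without regard to replicate number. In fat, chance can be excluded for the diet count (3999 real, 1 at most in the others, 1 split as large). The fat counts within lines were 1426 for low RFI (at most 54, 1 split) and 1398 for high RFI (at most 869, 1 split). For both of these chance can be excluded only if arrays are exchangeable across replicate numbers. The low RFI count was 839 without low RFI ad libitum replicate 4. The high RFI count was 757 without high RFI ad libitum replicate 5. For the diet effects that differ between tissues (1524, at most 875, 1 split) the splits remove the diet groups from both tissues. That comparison therefore does not separate a difference between tissues from the diet effect in fat itself. For the 42 shared calls (at most 0, 1 split) no other fat split had enough calls to share as many, so that comparison says nothing about sharing. For the next counts chance can be excluded only if arrays are exchangeable across replicate numbers, which the resemblance of arrays with the same number argues against. In fat these are line (3, at most 5, 2 splits) and line under ad libitum feeding (2, at most 4, 3 splits), which were 1 and 0 with the muscle covariate. In liver they are diet (144, at most 316, 2 splits), diet in low RFI (21, at most 82, 4 splits) and high RFI pigs (4, at most 2, 1 split), line (7, at most 19, 2 splits) and line under restriction (3, at most 18, 2 splits), and between tissues the line effects that differ (5, at most 43, 2 splits). The counts of 0 for the interactions, for line in liver under ad libitum feeding and for line in fat under restriction are met by all 100 splits whatever the data, so the splits say nothing about chance there (highest others 1379 in liver and 616 in fat for the interactions, 6 and 2 for line). The count for diet in high RFI liver was 0 with the replicate block and 0 without the intensity trend, so nothing is concluded from its split.

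For the number of called lists chance cannot be excluded. The splits compare only this number at the preset correlation, so they do not test any single list. As many lists were called for diet by 5 of 100 splits in liver (17 real, at most 20) and 10 in fat (14, at most 16), for line by 75 in liver (3, at most 16) and 19 in fat (11, at most 15), and for the interaction by 43 in liver (6, at most 13) and 85 in fat (4, at most 17). The liver splits with 316 calls for diet and 82 for diet in low RFI pigs part the arrays numbered 1 and 2 from the others as far as any split drawn (a difference in their share of 0.8), which points to a structure of the arrays that follows these numbers. The splits with 19 calls for line (0.6) and with 1379 liver and 616 fat calls for the interaction (-1.6) do so as well. The split with 869 calls in high RFI fat does not (0). Within numbers 1 and 2 the diet count in liver was 0 and the line count 4, within numbers 3 to 5 they were 44 and 2, and with the replicate block they were 328 and 8.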

How the results depend on the processing

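The alternatives that use the muscle covariate, the arrays with little muscle or liver signal, subsets of replicate numbers, or the block together with an estimated correlation were chosen after seeing the data, and the others were planned. With each array left out in turn the diet effect in fat passed for 3432 to 4547 probe sets against 3999, and quantile normalization, no filter, the stricter filter, the offset, no intensity trend, the block and the muscle covariate each gave at least 3478. Of the 3999 calls, 3248 also passed after quantile normalization, 3461 without the filter, 3277 with the stricter filter, 3993 with the offset, 3864 without the intensity trend and 3987 with the block. Of the 144 diet calls in liver, 138, 102, 132, 144, 73 and 144 did. For single genes, settings other than leaving an array out left 1050 values with the same direction and side of the threshold, moved 125 below and 9 above it and reversed 0. Leaving arrays out left 2585, moved 170 below and 5 above and reversed 0. For lists the counts were 380 unmoved, 141 below and 1 reversed, and 969 unmoved and 131 below with arrays left out. The reversed one is the result for list hepatocyte markers, diet in liver, whose median went from 0.11 to 0.00766 with a lower direction in the test after quantile normalization (adjusted p 0.956), and the cause was not tested. Signal over background limits the main filter, which left untested the probe sets that exceeded the 40th percentile on fewer than 5 arrays of a tissue. The setting without the filter tested all 23999 probe sets.

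With an estimated correlation, 1 list was called for diet in liver, 0 for line and 0 for the interaction there, and 0, 0 and 0 in fat. Together with the block these counts were 3, 0 and 0 in liver and 0, 0 and 0 in fat. Quantile normalization gave 3 lists for the interaction in liver and 7 for line in fat, and the stricter filter 7 for line in fat. Without the filter 1 probe set passed for line in fat. Without the intensity trend, 74 passed for diet in liver, 11 in low and 0 in high RFI pigs, and 24 calls were shared. The muscle covariate left 1 for line in fat and 0 under ad libitum feeding, and the arrays with little muscle or liver signal gave 391 for diet in high RFI fat and 0 for line in fat under ad libitum feeding. No low RFI restricted array was left among these, so the other fat effects could not be fitted. Numbers 1 and 2 alone gave 0 for diet and 4 for line in liver and 469 and 1 in fat, and numbers 3 to 5 gave 44 and 2 in liver and 2908 and 2 in fat. The cause of these changes was not tested.

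The replicate number as a block was among the planned settings. After removing group means, the correlation of arrays with the same number had a median of 0.183 in liver and 0.202 in fat, and 13 and 12 of 20 arrays were closest to one of their own number. With the block, counts were 328 for diet in liver, 66 in low and 0 in high RFI pigs, 8 for line in liver, 6 under restriction, and 5 lists for line in liver. In fat they were 5011 for diet, 2207 in low and 2184 in high RFI pigs, 20 for line and 1 under ad libitum feeding. With arrays of the same group and number taken as 1 pig (consensus correlation 0.214) the diet effect differed between tissues for 2296 probe sets and the line effect for 7, and under the replicate block 84 diet calls were shared between tissues. The labels do not identify the pigs, and for numbers 1 and 2 the best matched liver and fat arrays had the other number in 7 of 8 cases, so this block may join arrays of different pigs.

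Leaving out each array in turn gave these ranges. In liver, diet 56 to 203, line 5 to 9, interaction 0 to 1, diet in low RFI 7 to 28, diet in high RFI 0 to 7, line ad libitum 0 to 1, line restricted 0 to 5, and lists 15 to 20 for diet, 1 to 9 for line and 3 to 9 for the interaction. In fat, line 1 to 7, interaction 0 to 0, diet in low RFI 839 to 1624, diet in high RFI 757 to 2239, line ad libitum 0 to 3, line restricted 0 to 1, and lists 13 to 15 for diet, 5 to 12 for line and 2 to 7 for the interaction. Between tissues, diet 1276 to 1881 and line 2 to 8.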

Other observations

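The tests of the hypothesis in this part were chosen after the result was seen.

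Counts for further groups under restriction follow. In fat 6 of 15 thermogenesis and thyroid response genes fell and 1 rose (6 and 1 adjusted over the list alone), without a call for the list (camera adjusted p = 0.25). Glucocorticoid-responsive genes in fat had 4 of 18 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.124), against 1 of 20 lower in liver. The diet effect was higher in fat than in liver for 4 members of this list and lower for 1, and higher for 8 and lower for 2 of 32 extracellular matrix genes. Heat shock genes in fat had 5 of 17 lower and none higher (5 adjusted over the list alone, camera adjusted p = 0.0238, adjusted p = 0.681 with an estimated correlation, lost under 4 further alternatives, among them 0.124 after quantile normalization and 0.0697 without low RFI restricted replicate 5), and ribosomal proteins 3 of 61 higher and none lower (0 adjusted over the list alone, camera adjusted p = 0.0103, adjusted p = 0.786 with an estimated correlation, lost when either of 2 single arrays was left out, with values up to 0.115). In liver the proteasome list was called at a median of 0.11 (camera adjusted p = 0.000965, adjusted p = 0.277 with an estimated correlation, medians 0.14 and 0.05 within numbers 1 and 2 and within 3 to 5) and fatty acid oxidation at -0.10 (camera adjusted p = 0.00442, adjusted p = 0.18 with an estimated correlation, medians -0.12 and -0.09), with no member past the limma threshold (0 and 0 for the proteasome, 4 lower and 1 higher for oxidation adjusted over the list alone).

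Probe sets called for diet in opposite directions were 7 higher in liver and lower in fat (5.80 expected, Fisher's exact p = 0.513) and 8 the converse (11.2 expected, p = 0.335). Chosen after their values were seen, the named genes are the chaperone HSPA5, the prolyl isomerase FKBP11, ISOC2 and MDFIC among the 7, and fibrillin FBN1 and the actin-severing GSN among the 8. Means of cell type markers did not differ by diet or line in either tissue after adjustment over 34 tests (smallest adjusted p 0.454). The largest shifts by diet in fat apart from those of liver and muscle markers were endothelial (0.26, exact permutation p = 0.0621) and lymphocyte markers (0.20, p = 0.0646), both with an adjusted p of 0.454.

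The labels do not say that a liver and a fat array of the same number come from the same pig. A hypothesis is that they do for numbers 3 to 5 and that numbers 1 and 2 are exchanged between the tissues. Over 300 probe sets, all 12 liver arrays numbered 3 to 5 correlated best, within their group, with the fat array of their own number, and 7 of the 8 numbered 1 or 2 did so with the other of these numbers. In total 13 of 20 matched their own number (permutation p = 1e-04, the smallest that 10000 permutations can give). The permutation shuffled all numbers within a group, so it does not separate shared pigs from other effects that follow the numbers. It does not test the exchange of numbers 1 and 2 either. The pattern is consistent with that hypothesis, and no record of the animals was available to test it further.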
